A study of Mus musculus with 6 samples.

How the data were processed

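RNA-seq libraries from gastrocnemius samples of Tmem182 knockout (3 libraries) and wild-type (3 libraries) C57BL/6 mice were compared. Samples were grouped by the genotype recorded in the labels. The protocol text in the labels speaks of cultured muscle cells, while the tissue and source labels give skeletal muscle; the tissue label was followed.

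Each library had 1 table of 19458 genes with Entrez numbers and symbols. Per the file headers, each table gives a read count and an expression value per gene. The deposited counts are expected counts, since 26.2% to 27.5% of the values per library are not whole numbers, and they are not normalized. The deposited expression values are FPKM (fragments scaled by transcript length and library total), rounded to 2 decimals. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 were used with the GRCm38 build; roles and order are not given in the sources used here, and neither are read filters, the gene annotation or the handling of strand. RSEM divides reads that fit several transcripts by estimation, so genes with near-identical copies and genes that overlap an antisense gene are less certain than others.

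Expected counts were rounded to whole numbers, which moved no value by more than 0.5. Genes were kept by filterByExpr of edgeR with its minimum count of 10, which left 12774 genes, and libraries were scaled by TMM. The TMM factor was 1.19 for knockout library 1 and between 0.933 and 1.04 for the other 5. Groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No covariate and no replicate block was used. The common biological coefficient of variation was 18.8%. Standard errors are the absolute log2 fold change divided by the square root of the test's F, and intervals are at the 95% level. FPKM values are printed as deposited, and log2 fold changes come from the fit to counts. No 2 libraries agreed within counting noise: the chi-square per degree of freedom was at least 13.6 for every pair.

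Before the data were examined, 39 gene lists were fixed (muscle, signalling, metabolism, stress and cell type markers) with the tests, the alternatives and the rule for naming genes. Of the listed members, 5 had no match in the tables. Lists with at least 5 tested members, 36 in all, were tested with limma's camera (limma 3.58.1), two-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 36 lists; camera with an estimated correlation and fry were alternatives. Genes were also adjusted over each list alone. The naming rule took Tmem182 and its numbered relatives, a preset group of muscle genes, up to 12 called genes per direction with separate groups and at least 1 FPKM, the 5 genes with the smallest p per direction, and up to 4 members with the smallest p of each list described; some genes that the rule names are not reported here. Gene positions and overlaps come from GENCODE M21 on GRCm38, the build named in the submitters' processing notes.

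Alternatives were a replicate block, each library left out in turn, no filter, a mean of at least 5 FPKM, DESeq2 size factors, the DESeq2 Wald test (DESeq2 1.42.0), limma on log2(FPKM + 1), limma-voom with library quality weights and an adjusted p of 0.10. Chosen after seeing the data were the slow-fibre level as a covariate, 1 surrogate variable from sva 3.50.0 and limma-voom with equal weights. Alternatives planned for tables holding FPKM alone did not apply, since counts were given.

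The tests were tested on simulated data drawn from the means and library sizes of these libraries, for 3 knockout against 3 wild-type libraries and 12774 genes, with 200 changed genes, 100 for each size of change. Over 5 simulations edgeR recovered 55.8% of the genes changed 2-fold and 90.6% of those changed 4-fold, with 10.8 false calls on average; DESeq2 recovered 69.2% and 92.8%, with 30.4 false calls. A list shifted by 0.5 on the log2 scale was called in 5 of 5 simulations by camera with the preset correlation, in 4 with an estimated correlation and in 3 by fry, while unshifted lists were called 2, 0 and 0 times. Each simulated gene was drawn independently of the others. In the real libraries the estimated correlation within lists ran from -0.067 for the cell cycle to 0.90 for Schwann cell and myelin markers. For lists of correlated members the simulated counts therefore do not give the rate of false calls. Depth ranged from 16212341 to 18672630 expected counts per library.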

Results

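Tmem182 encodes a multi-pass membrane protein of striated muscle. The data were RNA-seq profiles of the gastrocnemius, the large calf muscle, from C57BL/6 mice aged 9 weeks, and the comparison asks which muscle transcripts differ when Tmem182 is knocked out. There were 3 libraries from knockout mice and 3 from wild-type mice, sequenced on a BGISEQ-500 instrument. Total expected counts ranged from 16212341 in knockout library 1 to 18672630 in wild-type library 2, and between 15620 and 16094 of the 19458 listed genes had a count above 0. Myh4, the myosin heavy chain of the fastest fibres, held the most counts in each of the 6 libraries. The 10 most abundant genes took 22.0% of the counts in knockout library 1 and between 28.2% and 31.9% in the other 5. The labels do not say that each library came from a separate mouse, so p-values measure only the spread between these samples, which may be technical in part; every pair of libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 13.6.

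Tmem182 fell from 129.9 ± 15.2 FPKM in wild type (SD, n = 3) to 4.23 ± 2.03 FPKM in the knockout (SD, n = 3). The gene (Entrez 381339) lies on chromosome 1 from 40805601 to 40856887 on the plus strand of GRCm38, with 1 annotated transcript of 5 exons spanning 2716 exonic bases, and no other annotated gene overlaps it. The wild-type libraries 1, 2 and 3 had 147.48, 121.39 and 120.97 FPKM, from 6487, 5596 and 5500 expected counts. The knockout libraries 1, 2 and 3 had 6.23, 4.30 and 2.17 FPKM, from 254, 196 and 98 expected counts, so a residue of 4.0%, 3.45% and 1.76% of the wild-type mean CPM remained. The log2 fold change was -5.02 (SE 0.30, 95% interval -5.72 to -4.32, adjusted p = 0.00391 by edgeR's quasi-likelihood test), and all 3 knockout libraries lay below all 3 wild-type libraries. The two-sided exact permutation test of the 6 log2 values gave p = 0.1, the smallest that 3 against 3 libraries allow. Without knockout library 2 the adjusted p was 0.0716 and without wild-type library 3 it was 0.0529, at log2 fold changes of -5.12 and -5.03.

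Source labels of knockout libraries 2 and 3 name other Tmem genes with the next higher numbers, while the genotype field names Tmem182 for all 3 knockout libraries. Tmem182 was low in all 3 of these libraries. Tmem183a was at 5.34 ± 0.44 FPKM in the knockout and 5.37 ± 0.44 in wild type (SD, n = 3 each; log2 fold change -0.01, SE 0.11). Tmem184b was at 15.2 ± 1.19 against 16.1 ± 2.41 FPKM (log2 fold change -0.15, SE 0.10) and Tmem184c at 2.53 ± 0.46 against 2.59 ± 0.16 FPKM (log2 fold change -0.07, SE 0.23). In knockout library 2 Tmem183a was at 5.3 FPKM, and in knockout library 3 Tmem184b was at 14.6 and Tmem184c at 2.71 FPKM. Wild-type libraries spanned 5.07 to 5.88, 13.9 to 18.65 and 2.4 to 2.7 FPKM for these 3 genes. Tmem184a was too low to be tested, at 0.27, 0.27 and 0.09 FPKM in the knockout libraries and 0.28, 0.20 and 0.27 FPKM in the wild-type libraries. Its lowest value was thus that of knockout library 3.

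**Figure D1:**
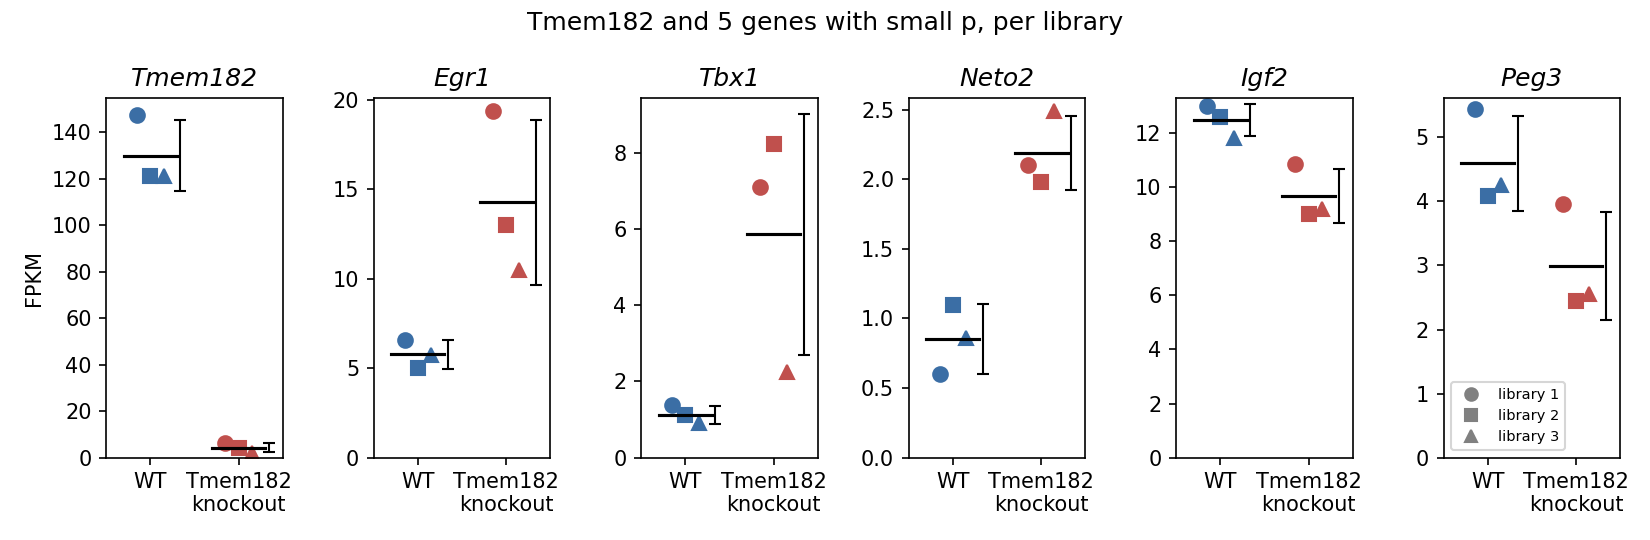
FPKM of Tmem182, Egr1, Tbx1, Neto2, Igf2 and Peg3 in the 3 wild-type libraries (blue) and the 3 Tmem182 knockout libraries (red), with a linear axis from 0 for each gene; symbols mark the library number, horizontal lines the group means and vertical bars 1 SD. Tmem182 lies between 120.97 and 147.48 FPKM in wild type and between 2.17 and 6.23 FPKM in the knockout. Of these genes only Tmem182 passed edgeR's adjusted threshold over the 6 libraries without a covariate, while DESeq2 called all 6.

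Of 12774 genes tested, Tmem182 was the only gene past an adjusted p of 0.05 in edgeR's quasi-likelihood test, so 0 genes rose and 1 fell. An unadjusted p under 0.05 was reached by 453 genes, 3.55% of those tested, 264 of them higher and 189 lower in the knockout. Chance alone would give 638.7 genes, more than were seen. DESeq2 called 6 genes: Tmem182, Peg3 and Igf2 lower, and Egr1, Tbx1 and Neto2 higher. With the slow-fibre level as a covariate in edgeR, Egr1 passed besides Tmem182 (adjusted p = 0.0292), and with 1 surrogate variable Egr1 (0.00663) and Peg3 (0.0391) did, both fits added after the data were seen. Counts of members past the threshold in the lists that follow are edgeR's without a covariate. The groups did not overlap for 1173 genes, 9.18% of those tested, where chance gives 10%.

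The 5 genes with the smallest p among those higher in the knockout did not pass edgeR's threshold without a covariate. Egr1, an immediate early transcription factor (chromosome 18, 34859823 to 34864984, plus strand), was at 19.38, 12.98 and 10.46 FPKM in the knockout libraries and 6.60, 5.01 and 5.71 FPKM in wild type (log2 fold change 1.22, SE 0.16, edgeR adjusted p = 0.483). Over all other fits its adjusted p ranged from 6.44e-07 to 1. Tbx1, a T-box transcription factor (chromosome 16, 18580979 to 18590671, minus strand), was at 7.11, 8.22 and 2.26 FPKM against 1.37, 1.11 and 0.90 FPKM (log2 fold change 2.28, SE 0.44, edgeR adjusted p = 0.994). Neto2, an auxiliary subunit of kainate receptors (chromosome 8, 85636588 to 85700924, minus strand), was at 2.19 ± 0.27 against 0.85 ± 0.25 FPKM (SD, n = 3 each), a log2 fold change of 1.31 (SE 0.26). Prkcd, a protein kinase C isoform, had a log2 fold change of 0.56 (SE 0.11) and Atp9a, a phospholipid-transporting ATPase, of 0.53 (SE 0.10). In these 5 genes every knockout library lay above every wild-type library.

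Among genes lower in the knockout, Igf2 and Peg3, a growth factor and a zinc-finger protein that are both expressed from the paternal allele, followed Tmem182. Igf2 (chromosome 7, 142650766 to 142666816, minus strand) was at 10.84, 8.99 and 9.19 FPKM in the knockout libraries and 13.01, 12.59 and 11.83 FPKM in wild type (log2 fold change -0.53, SE 0.08, edgeR adjusted p = 0.994). An antisense gene, Igf2os, and 2 genes on the same strand, the protein-coding Gm49394 and the microRNA gene Mir483, overlap Igf2. Counting by strand is not given in the sources used here, and it would not separate genes on the same strand. Peg3 (chromosome 7, 6703892 to 6730431, minus strand) was at 3.96, 2.44 and 2.56 against 5.45, 4.08 and 4.25 FPKM (log2 fold change -0.72, SE 0.13, edgeR adjusted p = 0.994). Tmem52, a membrane protein gene, had a log2 fold change of -0.42 (SE 0.09), and Grip1, a synaptic scaffold protein gene, of -1.44 (SE 0.31) at no more than 0.17 FPKM in any library. Antisense genes overlap Grip1 as well.

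Fibre-type transcripts varied widely between libraries of the same group. Slow fibre genes, which encode the contractile and calcium-handling proteins of oxidative type I fibres, had 19 of 20 tested members with a higher mean in the knockout and a median log2 fold change of 1.16, and 0 members passed the gene-level threshold over all genes or adjusted over the list alone. The list passed limma's camera test with a preset correlation (adjusted p = 0.00088), but not with the correlation estimated (adjusted p = 0.75 with an estimated correlation). Its mean log2 level was 7.64, 6.98 and 4.24 in the knockout libraries and 6.34, 3.94 and 6.16 in the wild-type libraries. The SD was 1.80 within the knockout, with a range of 3.40, and 1.33 within wild type. Group means differed by 0.80 (exact permutation p = 0.5). Myh7, the slow myosin heavy chain, was at 277.22, 196.42 and 1.34 FPKM in the knockout and 76.52, 5.71 and 71.59 FPKM in wild type (log2 fold change 1.5, SE 1.41). Antisense genes overlap Myh7, Myh1 and Myh2, and counting by strand is not given in the sources used here. Atp2a2, the slow calcium pump, had a log2 fold change of 1.5 (SE 0.88), the muscle LIM protein gene Csrp3 of 1.63 (SE 0.66), Fhl1 of 1.25 (SE 0.68) and Myl6b of 0.67 (SE 0.27). Without knockout library 1 the log2 fold changes of Csrp3 and Fhl1 were 1.03 and 0.16, and that of Csrp3 was 2.25 without wild-type library 1. The list's adjusted p was 0.465 without knockout library 1 and 0.511 without wild-type library 2.

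Fast fibre genes had 18 of 20 members with a lower mean in the knockout, with a median log2 fold change of -0.16 and 0 members past the gene-level threshold by either adjustment. Camera gave adjusted p = 0.0417 with the preset correlation (adjusted p = 0.85 with an estimated correlation). List means deviated from the mean of the 6 libraries by -0.43, 0.12 and 0.12 in knockout libraries 1, 2 and 3. Myh4 was at 6876.36, 13689.26 and 14156.32 FPKM in the knockout against 11905.24, 11621.72 and 14395.57 FPKM (log2 fold change -0.15, SE 0.41). Myh1 and Myh2, the chains of intermediate fast fibres, had log2 fold changes of 0.32 (SE 0.91) and 1.08 (SE 0.97), and among wild-type libraries alone Myh2 varied 15.6-fold. Without knockout library 1 the log2 fold changes of Myh1, Myh2 and Myh4 were -0.93, 0.0039 and 0.17. Mylk2, Casq1 and Atp2a1 had log2 fold changes of -0.39 (SE 0.25), -0.32 (SE 0.27) and -0.28 (SE 0.29). The direction of this list turned over without knockout library 1 (adjusted p = 0.657), and it did not pass without wild-type library 2 (adjusted p = 0.215), without wild-type library 3 (adjusted p = 0.211) or with no filter on low counts (adjusted p = 0.117).

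**Figure D2:**
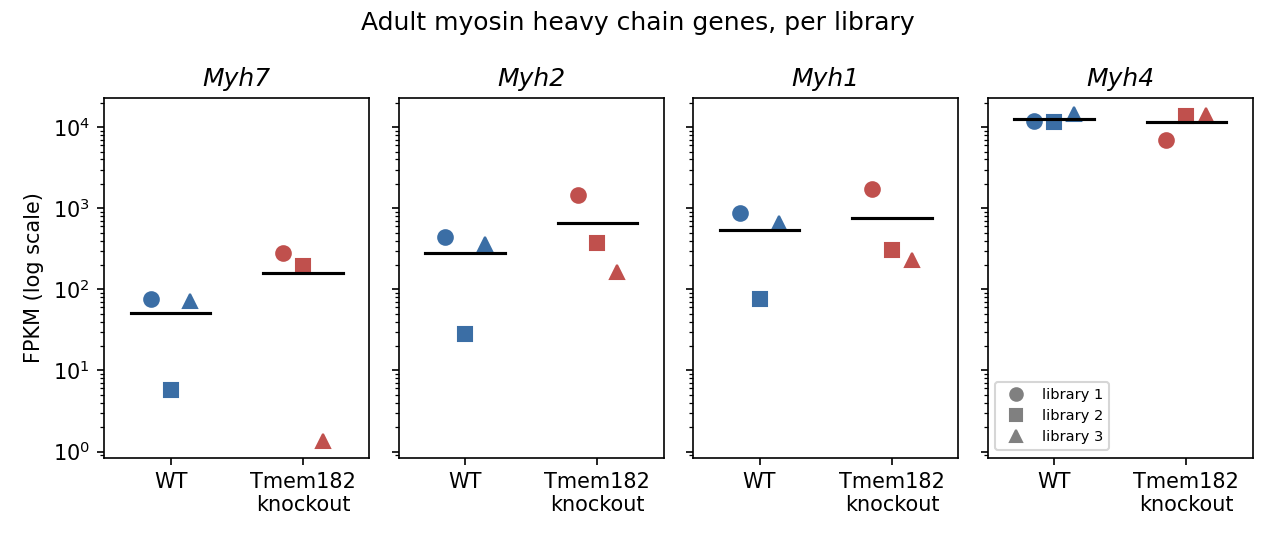
FPKM of the 4 adult myosin heavy chain genes, Myh7 (slow), Myh2, Myh1 and Myh4 (fast), in the 3 wild-type libraries (blue) and the 3 Tmem182 knockout libraries (red), on a log axis shared by the panels; symbols mark the library number and lines the group means. Myh7 runs from 1.34 to 277.22 FPKM within the knockout and from 5.71 to 76.52 FPKM within wild type, and Myh4 is lowest in knockout library 1, at 6876.36 FPKM.

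Sarcomere and Z-disc genes did not pass as a list (27 tested, median log2 fold change 0.13, camera adjusted p = 0.074), and 0 members passed. Xirp2, an actin-binding protein of the myotendinous and intercalated junctions, was at 217.62, 141.69 and 192.41 FPKM in the knockout and 111.74, 44.38 and 106.7 FPKM in wild type (log2 fold change 1.0, SE 0.33, edgeR adjusted p = 0.994). Smpx and Obsl1 had log2 fold changes of 0.28 (SE 0.11) and -0.36 (SE 0.16). Acta1, the skeletal alpha-actin, and Ckm, muscle creatine kinase, had log2 fold changes of -0.20 (SE 0.27) and -0.25 (SE 0.31). The list passed without wild-type library 1 (adjusted p = 0.0313) or library 3 (adjusted p = 0.0265).

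No named regulator of myogenesis passed the gene-level threshold. In the list of satellite cell and myogenic regulators 15 of 22 tested members had a lower mean in the knockout and 0 passed (median log2 fold change -0.10, camera adjusted p = 0.0755). Pax7, the satellite cell transcription factor, was at 0.95 ± 0.16 FPKM in the knockout and 1.27 ± 0.11 FPKM in wild type (SD, n = 3 each; log2 fold change -0.45, SE 0.18, edgeR adjusted p = 0.994). Myod1, Myog and Myf5 had log2 fold changes of 0.01 (SE 0.23), -0.27 (SE 0.23) and -0.25 (SE 0.29). Met had one of -0.33 (SE 0.15), Hes1 of 0.53 (SE 0.22) and Mef2c of 0.28 (SE 0.13). The list passed, downward, without wild-type library 2 (adjusted p = 0.0415) and with the slow-fibre level (0.0132) or 1 surrogate variable (0.018) as a covariate, and turned over with a mean of at least 5 FPKM (adjusted p = 0.687). The muscle fusion proteins' genes Mymk and Mymx were too low to be tested, with no library above 0.57 FPKM for Mymk or 0.16 FPKM for Mymx. The myoblast fusion list did not pass (25 tested, 0 past the threshold, median log2 fold change -0.03, mean 0.06, camera upward with adjusted p = 0.886). Its members with the smallest p were Itgb1, Adam12, Dock5 and Myof, at 0.28 (SE 0.14), 0.83 (SE 0.44), 0.45 (SE 0.46) and 0.29 (SE 0.30) on the log2 scale, and Adam12 and Dock5 lay at or below 0.43 FPKM in all 6 libraries. The fusion list turned over without knockout library 1 (adjusted p = 0.363) or wild-type library 2 (adjusted p = 0.421).

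Genes of embryonic and regenerating muscle also failed as a list (15 tested, camera downward with adjusted p = 0.0775), although their median log2 fold change of 0.07 and mean of 0.11 were above 0. By edgeR 2 members, Igf2 and Peg3, were lower when adjusted over the list alone, and 0 were called over all genes. DESeq2 called both over all genes (adjusted p = 0.0251 and 0.0224), and edgeR with 1 surrogate variable called Peg3 (0.0391). Actc1, cardiac alpha-actin, had a log2 fold change of -1.51 (SE 0.65), and Sln, the calcium-pump regulator sarcolipin, of 1.78 (SE 0.86), or 0.87 without knockout library 2 and 2.45 without wild-type library 2. The embryonic and perinatal myosins Myh3 and Myh8 were at or below 2.98 and 2.64 FPKM in all libraries, with log2 fold changes of 0.71 (SE 0.85) and 0.37 (SE 0.47), or -0.89 and -0.28 without knockout library 1. The list passed, downward, without knockout library 1 (adjusted p = 0.00608) or wild-type library 2 (0.00683), and with the slow-fibre level (0.00627) or 1 surrogate variable (0.00683) as a covariate.

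Adhesion and matrix genes did not pass as lists in the main fit. Of 29 integrin adhesion genes 0 passed (median log2 fold change -0.00, mean 0.03, camera upward with adjusted p = 0.685). Itgb1, integrin beta 1, was at 41.9 ± 11.9 FPKM in the knockout and 32.5 ± 4.17 FPKM in wild type (SD, n = 3 each; log2 fold change 0.28, SE 0.14), with knockout library 1 at 55.57 FPKM. Itga7, the muscle laminin receptor, had a log2 fold change of 0.08 (SE 0.10), Itgav of 0.26 (SE 0.15), Cd151 of 0.25 (SE 0.10), Lims1 of 0.41 (SE 0.20) and Ptk2, focal adhesion kinase, of -0.10 (SE 0.08). Of 37 extracellular matrix genes 0 passed (median log2 fold change 0.12, camera upward with adjusted p = 0.108). Tnc, tenascin C, was at 1.87, 1.16 and 0.75 FPKM in the knockout against 2.21, 2.01 and 1.99 FPKM (log2 fold change -0.80, SE 0.23, edgeR adjusted p = 0.994). Col14a1, Loxl1 and Lama2 had log2 fold changes of 0.78 (SE 0.34), 0.45 (SE 0.21) and 0.31 (SE 0.15). The matrix list passed upward without knockout library 2 (adjusted p = 0.000166), knockout library 3 (adjusted p = 0.0125) or wild-type library 1 (adjusted p = 0.000312), and turned over without knockout library 1 (adjusted p = 0.0976) or wild-type library 2 (adjusted p = 0.215). The integrin list turned over without knockout library 1 (adjusted p = 0.454) or wild-type library 2 (adjusted p = 0.286).

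Growth and atrophy pathways gave 3 further lists that did not pass in the main fit. Among 27 insulin, IGF and Akt-mTOR genes, 0 passed over all genes by edgeR and 1, Igf2, by DESeq2 (adjusted p = 0.0251), and by edgeR it was lower when adjusted over the list alone (median log2 fold change 0.05, camera adjusted p = 0.858). Igf1 had a log2 fold change of 0.32 (SE 0.33), Igfbp3 of -0.62 (SE 0.23) and Rictor of -0.26 (SE 0.13). Among 28 myostatin, activin and BMP genes 0 passed (median log2 fold change 0.01, mean 0.01, camera downward with adjusted p = 0.702). Mstn, the growth inhibitor myostatin, and its antagonist Fst had log2 fold changes of 0.03 (SE 0.35) and -0.03 (SE 0.36), and the activin receptors Acvr1b and Acvr2b of -0.57 (SE 0.24) and 0.24 (SE 0.14). Fstl3 and Smad1 had log2 fold changes of 0.56 (SE 0.30) and -0.19 (SE 0.12). Among 27 muscle atrophy genes 0 passed (median log2 fold change 0.00, camera adjusted p = 0.89). Fbxo32, the ubiquitin ligase atrogin-1, was at 52.08, 70.18 and 32.34 FPKM in the knockout and 28.32, 19.90 and 31.56 FPKM in wild type (log2 fold change 0.89, SE 0.30, edgeR adjusted p = 0.994), and Trim63, the ubiquitin ligase MuRF1, had a log2 fold change of 0.20 (SE 0.20). Gadd45a, Bnip3 and Gabarapl1 had log2 fold changes of -0.47 (SE 0.14), 0.25 (SE 0.10) and 0.35 (SE 0.19). Directions turned over for the growth list without knockout library 2 (adjusted p = 0.52) or wild-type library 1 (0.87), for the myostatin list without wild-type library 1 (0.954), and for the atrophy list without knockout library 1 (0.994), knockout library 2 (0.889) or wild-type library 2 (0.642).

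Immediate early genes, the transcripts induced within minutes of a stimulus, passed as a list with the preset correlation (26 tested, median log2 fold change 0.21, camera adjusted p = 0.00674; adjusted p = 0.75 with an estimated correlation). By edgeR 1 member, Egr1, was higher when adjusted over the list alone, and 0 were called over all genes. Egr1 was called over all genes by DESeq2 (adjusted p = 6.44e-07) and by edgeR with the slow-fibre level (0.0292) or 1 surrogate variable (0.00663) as a covariate. Junb, Socs3 and Arc had log2 fold changes of 0.62 (SE 0.17), 1.24 (SE 0.35) and 0.90 (SE 0.38). The list mean of knockout library 1 lay 0.60 above the mean of the 6 libraries and those of knockout libraries 2 and 3 at -0.03 and -0.22, and without knockout library 1 the direction turned over (adjusted p = 0.977). The list did not pass without wild-type library 2 (adjusted p = 0.0665) or 3 (adjusted p = 0.0765), or with a mean of at least 5 FPKM (adjusted p = 0.0848). The ERK feedback targets did not pass (15 tested, median log2 fold change 0.01, camera adjusted p = 0.369), and Egr1 was again the 1 member called when adjusted over the list alone. Myc, Dusp6 and Ccnd1 had log2 fold changes of -0.72 (SE 0.30), 0.43 (SE 0.24) and 0.24 (SE 0.14). The ERK list turned over without wild-type library 2 (adjusted p = 0.948).

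Fatty acid oxidation genes had a higher mean in the knockout for 31 of 31 tested members, with a median log2 fold change of 0.25 and 0 members past the gene-level threshold by either adjustment. The list passed with the preset correlation (camera adjusted p = 2.99e-06; adjusted p = 0.75 with an estimated correlation). Pdk4, the kinase that switches off pyruvate oxidation, was at 148.62, 96.35 and 12.16 FPKM in the knockout and 25.57, 8.80 and 27.74 FPKM in wild type (log2 fold change 1.91, SE 0.76). Angptl4, Acot2 and Ucp3 had log2 fold changes of 2.37 (SE 0.94), 0.65 (SE 0.27) and 0.74 (SE 0.33), and that of Angptl4 was 0.80 without knockout library 1 and 3.03 without wild-type library 1. List means deviated from the mean of the 6 libraries by 0.76, 0.21 and -0.34 in the knockout and by 0.11, -0.78 and 0.04 in wild type. The list no longer passed without knockout library 1 (adjusted p = 0.16) or without wild-type library 2 (adjusted p = 0.286).

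Heat shock and chaperone genes had a higher mean for 19 of 21 members (median log2 fold change 0.22, camera adjusted p = 3.38e-06; adjusted p = 0.75 with an estimated correlation), and 0 passed by either adjustment. Hspa5, the chaperone of the endoplasmic reticulum, had a log2 fold change of 0.32 (SE 0.10), Hspa8 of 0.35 (SE 0.16), Hspd1 of 0.29 (SE 0.14) and Chordc1 of 0.22 (SE 0.08). The list mean deviated by 0.59 in knockout library 1 and by between -0.21 and 0.00 in the other 5 libraries, and without knockout library 1 the adjusted p was 0.0976.

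Markers of other cell types also differed between libraries. Macrophage markers had a higher mean in the knockout for 18 of 18 tested members, with a median log2 fold change of 0.63 and 0 members past the gene-level threshold by either adjustment (camera adjusted p = 6.73e-08; adjusted p = 0.75 with an estimated correlation). Lyz2, the macrophage lysozyme, was at 26.43, 8.52 and 11.96 FPKM in the knockout and 9.64, 6.03 and 5.33 FPKM in wild type (log2 fold change 1.05, SE 0.35), and Laptm5, Adgre1 and Ctss had log2 fold changes of 0.75 (SE 0.30), 0.93 (SE 0.38) and 1.2 (SE 0.55), with Ctss at 0.52 without knockout library 1. List means of the macrophage markers deviated by 0.93, -0.21 and 0.14 in the knockout and by -0.06, -0.39 and -0.41 in wild type (exact permutation p = 0.2). The macrophage list passed in each fit without 1 library. With a mean of at least 5 FPKM it had fewer than 5 members left and was not tested. Adipocyte markers had a higher mean for 15 of 15 members, with a median log2 fold change of 1.19 (camera adjusted p = 2.13e-05; adjusted p = 0.75 with an estimated correlation). Thrsp, a lipogenic regulator, was the 1 member called when adjusted over the list alone, at 13.98 ± 1.60 against 9.39 ± 0.39 FPKM (SD, n = 3 each; log2 fold change 0.50, SE 0.10), and 0 passed over all genes. Adipoq, the adipocyte hormone adiponectin, was at 10, 0.78 and 2.99 FPKM in the knockout and 1.17, 1.45 and 1.09 FPKM in wild type, and Cfd and Retn had log2 fold changes of 1.44 (SE 0.53) and 1.48 (SE 0.64). Without knockout library 1 the log2 fold change of Adipoq was 0.64, against 1.71 with it, and that of Cfd was 0.66. List means of the adipocyte markers deviated by 1.38, -0.60 and 0.27 in the knockout and by -0.08, -0.48 and -0.49 in wild type, and without knockout library 1 the adjusted p was 0.116.

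Schwann cell and myelin markers had a median log2 fold change of 0.56 over 18 members with 0 past the threshold (camera adjusted p = 0.0012; adjusted p = 0.75 with an estimated correlation). Their list means deviated by 1.24, -0.28 and 0.02 in the knockout and by 0.96, -1.36 and -0.60 in wild type. Egr2, Dhh and Cdh19 had log2 fold changes of 0.68 (SE 0.40), 0.62 (SE 0.50) and 0.91 (SE 0.96), all at or below 0.83 FPKM. Cdh19 was at 3.46 without wild-type library 1 and at 0.40 without wild-type library 2, and Dhh at -0.081 without knockout library 1. The list's adjusted p was 0.465 without knockout library 1 and 0.607 without wild-type library 2. With a mean of at least 5 FPKM the Schwann cell list had fewer than 5 members left and was not tested. Tendon markers had a lower mean for 17 of 17 members, with a median log2 fold change of -0.45 and 0 members past the threshold (camera adjusted p = 0.000445; adjusted p = 0.75 with an estimated correlation). Besides Tnc, Ptx4, Col11a2 and Col22a1 had log2 fold changes of -0.78 (SE 0.35), -0.46 (SE 0.22) and -0.40 (SE 0.21). List means deviated by 0.29, -0.40 and -0.47 in the knockout and by 0.69, -0.57 and 0.46 in wild type, and without wild-type library 1 the adjusted p was 0.119, and with a mean of at least 5 FPKM it was 0.157.

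A fixed list of neighbours of Tmem182 on chromosome 1 had a median log2 fold change of 0.16 over 25 tested members, and 0 passed. Its farthest member lies 3.26 Mb from Tmem182. The list was written beforehand and was not drawn from the annotation, so it does not stand for every gene in that interval. Camera gave adjusted p = 0.00999 with the preset correlation and 0.75 with an estimated correlation. The estimated correlation of this list was -0.018, below the preset 0.01, so the higher adjusted p cannot be read as correlation among its own members. Camera with an estimated correlation gave the same adjusted p of 0.75 to Schwann cell and myelin markers, whose estimated correlation was 0.90. That adjusted p therefore does not tell these lists apart. Slc9a2, a sodium-proton exchanger gene 0.0363 Mb from Tmem182, was at 18.72, 16.15 and 14.56 FPKM in the knockout and 13.92, 9.64 and 13.19 FPKM in wild type (log2 fold change 0.36, SE 0.14). Mfsd9, the nearest listed gene at 0.0149 Mb, was at or below 0.51 FPKM in all libraries (log2 fold change 0.88, SE 0.36). Map4k4 and Fhl2 had log2 fold changes of 0.26 (SE 0.12) and 1.77 (SE 0.88), and Fhl2 was at 0.47 without knockout library 1. The list mean of knockout library 1 deviated by 0.34, and the list did not pass without that library (adjusted p = 0.114) or with a mean of at least 5 FPKM (adjusted p = 0.121).

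In all, 17 of 36 tested lists passed camera with the preset correlation, 13 higher and 4 lower in the knockout. None passed with an estimated correlation, where the lowest adjusted p was 0.75, and none passed fry, where it was 0.859. Knockout library 1 had the largest deviation of the 6 libraries in 12 of the 17 lists. Without it 6 lists passed, of which 2, the macrophage and tendon markers, were among the 17 in the same direction. Without wild-type library 2 the count was 11, with 8 of the 17 in the same direction. With the slow-fibre level as a covariate, added after the data were seen, 11 lists passed, 8 of them among the 17 in the same direction. The fast fibre (adjusted p = 0.359), Schwann cell (0.0854) and immediate early (0.127) lists were among those that did not, and the outcome for the slow-fibre list itself (0.443) was fixed by the covariate. With 1 surrogate variable, also added later, 9 lists passed, 6 of them among the 17, without the fast fibre (adjusted p = 0.339), slow fibre (0.0892), Schwann cell (0.232), immediate early (0.517) and chromosomal neighbour (0.0661) lists.

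**Figure D3:**
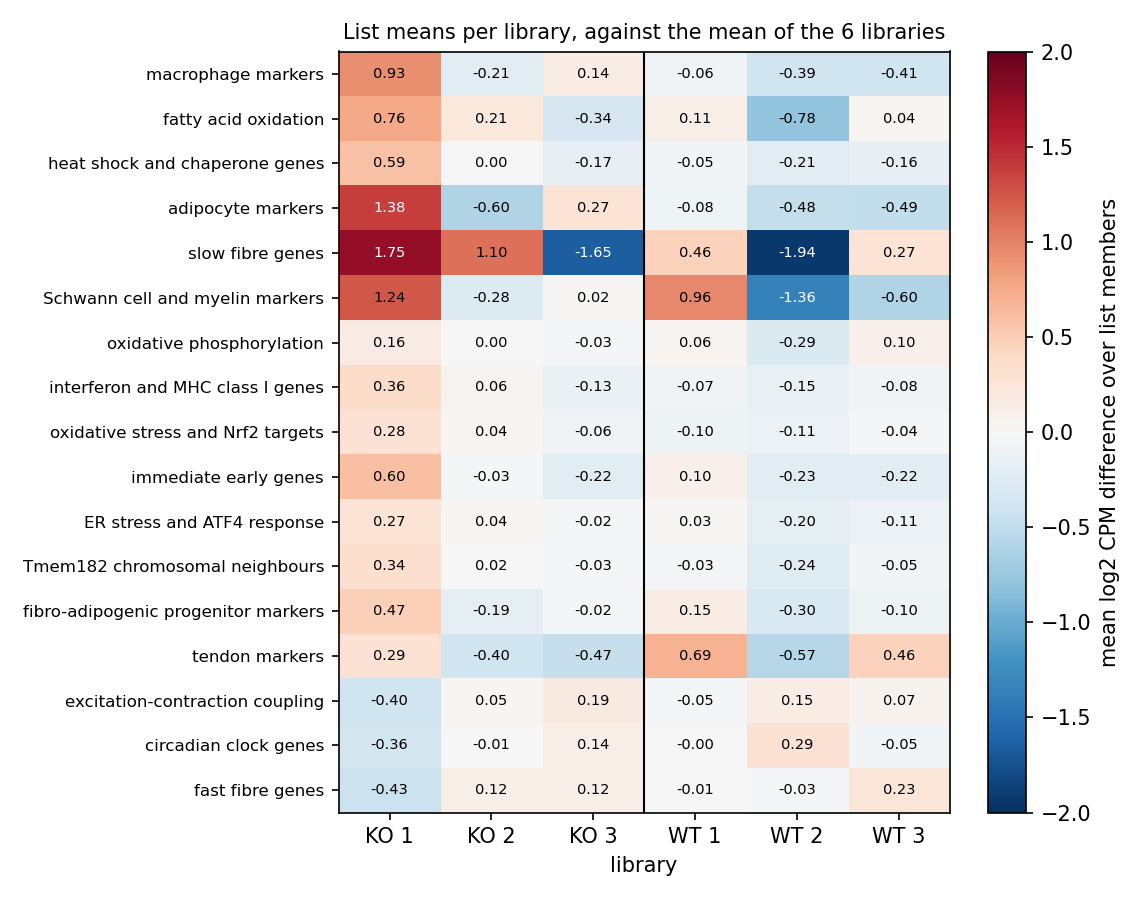
Mean log2 CPM over the members of each of the 17 gene lists that passed camera with the preset correlation, as a difference from the mean of the 6 libraries, for the 3 Tmem182 knockout (KO) and 3 wild-type (WT) libraries; lists higher in the knockout come first, the 4 lower ones last. Slow fibre genes range from -1.94 in wild-type library 2 to 1.75 in knockout library 1, and knockout library 1 has the largest deviation in 12 of the 17 lists.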

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

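Tests chosen only after the data were seen were the fits with the slow-fibre level, 1 surrogate variable, or limma-voom with equal weights. The log2 fold change of Tmem182 was -5.26 to -4.72 over 16 alternative fits; it passed in 14 and missed in the fits without knockout library 2 or wild-type library 3 (adjusted p 0.0716 and 0.0529), and over the fits without 1 library it ran from -5.26 to -4.75. Fits without 1 library called 0 to 1 genes and 6 to 19 lists. Other fits called 1 gene, except DESeq2 (6 genes), the slow-fibre covariate (2, with Egr1) and the surrogate variable (3, with Egr1 and Peg3). Lists called were 10 with a mean of at least 5 FPKM, 11 with the slow-fibre covariate, 9 with the surrogate variable, and 0 with an estimated correlation or fry. With a mean of at least 5 FPKM the macrophage and Schwann cell lists had too few members to be tested. The replicate block gave 1 gene and 20 lists. The 3 lists it added were satellite cell and myogenic regulators (adjusted p 0.0429), sarcomere and Z-disc structure (0.0335) and extracellular matrix (0.00873). Direction changed with the block for Mstn, at -0.094, and smooth muscle and pericyte markers (0.956). Deviations of knockout libraries 1 and 2 correlated best with the wild-type library of equal number (0.52 and 0.18). Those of knockout library 3 correlated best with wild-type library 2 (0.43), against -0.12 with wild-type library 3. Whether equal numbers pair the libraries stays open. Over 1526 gene values 1474 kept direction and side of the threshold, 8 came to pass and 44 changed direction, and over 500 list values 338, 23 and 54, with 85 no longer passing. Fits without 1 library that changed direction spanned, in log2: Tmem183a -0.060 to 0.072, Tmem184c -0.23 to 0.16, Myod1 -0.22 to 0.21, Igf1 -0.0012 to 0.66, Mstn -0.32 to 0.37, Fst -0.49 to 0.26, Myh1 -0.93 to 0.77, Myh3 -0.89 to 1.19, Myh4 -0.37 to 0.17, Myh8 -0.28 to 0.70, Dock5 -0.093 to 0.90, Myof -0.14 to 0.49, Dhh -0.081 to 0.96. For lists the adjusted p spanned: ERK feedback targets 0.071 to 0.994, excitation-contraction coupling 2.07e-05 to 0.574, extracellular matrix 0.000166 to 0.215, fast fibre genes 0.00474 to 0.657, fibro-adipogenic progenitor markers 1.03e-05 to 0.956, immediate early genes 4.55e-05 to 0.977, insulin, IGF and Akt-mTOR growth signalling 0.354 to 0.87, integrin adhesion 0.0751 to 0.604, muscle atrophy 0.515 to 0.994, myoblast fusion 0.202 to 0.953, myostatin, activin and BMP signalling 0.451 to 0.954, oxidative phosphorylation 7.25e-07 to 0.447, cell cycle 0.642 to 0.969, denervation response 0.258 to 0.994, endothelial markers 0.0047 to 0.572, glucocorticoid and fasting response 0.188 to 0.994, glycolysis and glycogen 0.103 to 1.0, ribosomal proteins 9.11e-05 to 0.607, smooth muscle and pericyte markers 0.116 to 0.851. With quality weights (0.297 for knockout library 1) the direction changed for Myh1 (-0.71), Myh3 (-0.65), Myh7 (-0.26), Myh8 (-0.36), Myof (-0.037), Tmem183a (0.081) and Tmem184c (0.063); with the slow-fibre covariate for Myh1 (-0.16), Myh3 (-0.14), Myh7 (-1.10), Myod1 (-0.018) and Tmem183a (0.028), and for extracellular matrix (adjusted p 0.698), integrin adhesion (0.487), muscle atrophy (0.902), myoblast fusion (0.359), denervation response (0.698), glycolysis and glycogen (0.666) and ribosomal proteins (0.257); with the surrogate variable for Myh1 (-0.44), Myh3 (-0.39), Myh8 (-0.032), Myod1 (-0.062), Tmem183a (0.039) and Tmem184c (0.021), and for extracellular matrix (0.342), integrin adhesion (0.339), myoblast fusion (0.232), denervation response (0.77), glycolysis and glycogen (0.448) and ribosomal proteins (0.0844); with a mean of at least 5 FPKM for denervation response (0.507), myoblast fusion (0.831) and satellite cell and myogenic regulators (0.687); for smooth muscle and pericyte markers with no filter (0.943) or fry (0.9747); and for Mstn with limma on log2(FPKM + 1) (-0.034) and limma-voom with equal weights (-0.10). Alternatives planned for FPKM alone or for limma as the main test were not run, since counts were used. Fits without 1 library also rest on fewer libraries, and neither this nor any other cause of the changes was tested. Without knockout library 2 or 3, all 17 lists called in the main fit still passed in the same direction.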

Other observations

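Tests chosen only after the result was seen were those of the share of muscle fibre RNA, of the genotype as the whole slow-fibre difference, of the share of unadjusted p-values under 0.05, and the fits with the slow-fibre level or a surrogate variable as a covariate.

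Several further lists passed camera with the preset correlation, with 0 members past the gene-level threshold in each. Oxidative phosphorylation genes had a median log2 fold change of 0.06 (camera adjusted p = 0.00342; adjusted p = 0.85 with an estimated correlation), with list deviations of 0.16, 0.00 and -0.03 in the knockout and 0.06, -0.29 and 0.10 in wild type. Interferon and MHC class I genes had a median of 0.16 (adjusted p = 0.00342; adjusted p = 0.75 with an estimated correlation), Nrf2 targets of the oxidative stress response 0.14 (adjusted p = 0.00342; adjusted p = 0.75 with an estimated correlation), genes of the ER stress and ATF4 response 0.15 (adjusted p = 0.00674; adjusted p = 0.75 with an estimated correlation) and markers of fibro-adipogenic progenitors 0.19 (adjusted p = 0.0109; adjusted p = 0.75 with an estimated correlation). Excitation-contraction coupling genes had a median of -0.12 (adjusted p = 0.00707; adjusted p = 0.78 with an estimated correlation) and circadian clock genes of -0.17 (adjusted p = 0.0237; adjusted p = 0.75 with an estimated correlation). The list mean of knockout library 1 deviated from the mean of the 6 libraries by 0.36 for interferon genes, 0.28 for Nrf2 targets, 0.27 for the ER stress response, 0.47 for progenitor markers, -0.40 for coupling genes and -0.36 for clock genes. Without that library none of these 7 lists passed, with adjusted p from 0.116 for the Nrf2 and ER stress lists to 0.956 for the progenitor and clock lists, and the coupling and progenitor lists turned over. Without wild-type library 2 the oxidative phosphorylation list turned over (adjusted p = 0.245) and the coupling (0.0931), progenitor (0.286) and clock (0.313) lists did not pass. The Nrf2 list did not pass without wild-type library 1 (adjusted p = 0.0866), nor the coupling and progenitor lists without wild-type library 3 (0.0629 for each). With a mean of at least 5 FPKM the interferon (adjusted p = 0.183) and clock (0.0703) lists did not pass. The slow-fibre covariate ended the calls of the oxidative phosphorylation (adjusted p = 0.424), interferon (0.0989), progenitor (0.145), coupling (0.348) and clock (0.308) lists, and the surrogate variable ended these (0.453, 0.121, 0.339, 0.339 and 0.453) and that of the ER stress list (0.0661).

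Lists that did not pass camera, each with 0 members called over all genes by edgeR, were endothelial markers (median log2 fold change 0.02, mean -0.00, camera downward with adjusted p = 0.459), smooth muscle and pericyte markers (median 0.01, mean 0.04, camera downward with adjusted p = 0.98), erythroid genes (median -0.10, adjusted p = 0.136), the denervation response (0.12, adjusted p = 0.886), the dystrophin complex and costamere (0.02, adjusted p = 0.265), glycolysis and glycogen (-0.08, adjusted p = 0.647), glucocorticoid and fasting response (median 0.03, mean 0.15, camera downward with adjusted p = 0.824), the cell cycle (0.04, adjusted p = 0.702) and ribosomal proteins (-0.03, adjusted p = 0.196). Endothelial markers passed, downward, without knockout library 1 (adjusted p = 0.0047) or wild-type library 2 (0.00703) and with the slow-fibre level (1.58e-05) or 1 surrogate variable (5.42e-05) as a covariate, and turned over without knockout library 3 (0.0703) or wild-type library 1 (0.408). Erythroid genes passed, downward, without knockout library 1 (adjusted p = 0.00103), and the cell cycle list passed, upward, with no filter on low counts (0.00781). Ribosomal proteins passed, downward, without knockout library 3 (adjusted p = 9.11e-05) or wild-type library 1 (0.000286), and upward without knockout library 1 (0.0411). Other changes of direction were those of the cell cycle without knockout library 1 (adjusted p = 0.927) or wild-type library 2 (0.642), the denervation response without knockout library 2 (0.889) or wild-type library 2 (0.258), glycolysis without knockout library 1 (0.116) or wild-type library 2 (1.0), the glucocorticoid response without knockout library 2 (0.994), knockout library 3 (0.618) or wild-type library 1 (0.745), ribosomal proteins without wild-type library 2 (0.607), and smooth muscle markers without knockout library 2 (0.573), knockout library 3 (0.618), wild-type library 1 (0.394) or wild-type library 3 (0.851). Neutrophil, lymphocyte and sex-linked lists had 2, 3 and 4 tested members, too few for the test.

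For the lists passing camera, weighed first, the real split gave 17 and the highest of the other splits 22. Of the 10 splits, 4 gave at least 17 lists, the real split among them. So many lists can thus be called without a split by genotype, and 10 splits are too few for a share under 0.05. If knockout library 1 alone set the calls, fewer than 9 of the 17 would remain without it, and 2 remained in the same direction, as that explanation needs; 8 remained without wild-type library 2, 15 without wild-type library 1, 13 without wild-type library 3 and 17 without knockout library 2 or 3, so that a part of wild-type library 2 in the calls stays open. A lower share of muscle fibre RNA in knockout library 1 would raise the markers of other cell types alike. Over the mean of the other 5 libraries their medians ran from 0.34 for endothelial markers to 1.87 for adipocyte markers, a difference of 5.04 times its standard error over members. That multiple cannot decide, since the lists were picked as the highest and lowest, and genes of 1 library are not independent. Slow fibre genes were higher in knockout library 1 by a median of 2.18. Over the same 5 libraries the median was 0.176 for sarcomere and Z-disc genes and -0.846 for fast fibre genes. The lists of fibre genes thus did not all fall in that library. With the slow-fibre level as a covariate 8 of the 17 lists passed in the same direction. Passing with the covariate would speak against slow-fibre content as the source of those 8. Camera with the preset correlation also called up to 22 lists in other splits, fitted without that covariate. A pass in this test therefore cannot decide, and slow-fibre content as the source of those 8 stays open. For the slow-fibre list itself the covariate fixes the outcome. The share of muscle fibre RNA in knockout library 1, the part of the muscle taken, its content of interstitial cells and genotype stay open.

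Genes past the threshold numbered 1 in the real split and 4 in the highest of the other splits, and 10 splits are too few for a share under 0.05. The split with 4 set knockout library 1 and wild-type libraries 1 and 3 against the rest, with 2061 unadjusted p under 0.05.

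The residual Tmem182 reads in the knockout were weighed second. Reads shared with other genes are argued against: of the 2667 words of 50 bases in the annotated transcript, 0, or 0%, occur in transcripts of another gene. Reads carried over from the wild-type libraries cannot be told apart from transcript left in the muscle: a mixture of 4.84%, 3.36% and 1.69% of wild-type reads would give the counts of knockout libraries 1, 2 and 3, and 0 other genes fell below what it would bring, but apart from Tmem182 no gene was called lower by edgeR without a covariate, so the test had little to decide on. Whether the residue comes from exons outside a deleted part was not tested, since counts per exon were not used here.

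Igf2 and Peg3, both lower in all 3 knockout libraries, were weighed last, with the hypothesis of a shared fall of the imprinted gene network. Of 15 other measured genes of the network, listed before this test was run, 8 were lower, 0 had an unadjusted p under 0.05, and the median log2 fold change was -0.036 (bootstrap SE 0.0863), at percentile 20.8 of 10000 random lists matched on expression and above their 5th percentile of -0.0821. A fall of the whole network by the size seen for Igf2 is argued against. A fall of these 2 genes alone, or chance, stays open, since edgeR's adjusted p was 0.994 for each and DESeq2 gave 0.0251 for Igf2 and 0.0224 for Peg3, within ranges over all fits of 0.0251 to 1 and 0.0224 to 1.

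The range of the slow-fibre list mean within a group reached 3.40 on the log2 scale against a difference of 0.80 between group means. A range over few libraries tends to exceed a difference of means, so this comparison says little about genotype. The slow-fibre level and the total count had Pearson r = -0.72 (exact permutation p = 0.0764) and Spearman rho = -0.71 (exact permutation p = 0.136) over 6 libraries in 1 relation computed, and r = 0.03 without knockout library 1 and wild-type library 2, on which the relation rests; the bound set beforehand, a p of 0.05 or more, was too loose to exclude it with 6 libraries. An unadjusted p under 0.05 was reached by 3.55% of tested genes in the real split, and by 135 to 2061 genes in the other splits against 453 in the real split. Chance alone would give 638.7 genes. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 6 libraries, Eif2s3y at 11.13 to 14.11 FPKM.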
